A study of Mus musculus with 15 samples.

How the data were processed

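Gene expression was measured in mesenchymal cells of C57BL/6 mice aged 2 weeks. Cells were sorted as PDGFRβ-positive subsets after digestion with liberase and DNase I. The thymus gave a PDPN+BP3- population and a PDPN- population, and pooled inguinal, brachial and axillary lymph nodes gave PDPN+BP3-, PDPN+BP3+ and PDPN- populations. PDPN is podoplanin, BP3 is the product of Bst1, and both PDPN- populations were also sorted as Ly51-positive, Ly51 being the product of Enpep. Each of the 5 populations was measured on 3 arrays from 3 individual experiments that used separate pools of mice, so n = 3 for every population and 15 arrays in all. A pool held 3 mice for thymus and 10 to 11 mice for lymph node, so pool size cannot be told apart from tissue. RNA was isolated with a column kit for small samples, amplified with the Ovation Pico WTA System V2 and measured on Mouse Gene 1.1 ST arrays of Affymetrix.

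The deposited values were RMA signal intensities on a log2 scale, which the authors made with the Affymetrix Expression Console. The versions of RMA and of the console are not given in the sources used here. The labels do not name the log base, and base 2 was inferred from the range of the values, 1.07 to 12.07 with a median of 3.80. The precision of the values is limited by the number of arrays. The deposited table held 24758 transcript clusters, and all of its 15 columns were assigned to an array by their titles. Gene symbols came from the array annotation: 20844 transcript clusters had 1 symbol, 1735 had several and 2179 had none in the annotation used. Of those with 1 symbol, 20817 were found in a mouse gene table by gene identifier and 0 symbols changed. For 1230 genes with more than 1 transcript cluster, the one with the highest mean over all arrays was kept and 2126 others were left out, so 18718 genes were tested. No filter on low values was applied. No measure of background was used here. In 309 of the 629 named pairs of gene and comparison past the threshold, the population with the lowest mean lay below the median of the table, where a value need not stand above background. Such log2 differences are differences of signal, and no ratio of RNA was derived from them.

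Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per population was fitted over all 15 arrays, and moderated statistics were computed with empirical Bayes shrinkage without a trend (residual degrees of freedom 10, prior degrees of freedom 5.50). P-values were adjusted with the Benjamini-Hochberg method over all genes of a comparison, and the threshold was an adjusted p of 0.05. The 6 pairwise comparisons were PDPN+BP3- against PDPN- in thymus and in lymph node, PDPN+BP3+ against PDPN- and against PDPN+BP3- in lymph node, and lymph node against thymus in PDPN+BP3- and in PDPN- cells. The interaction tested whether the difference between PDPN+BP3- and PDPN- cells differed between lymph node and thymus. The lymph node comparisons against PDPN- cells use the same 3 PDPN- arrays, so their calls were not compared with each other. The comparison of the subsets in thymus shares no array with that in lymph node, and the comparisons of the tissues share none either, so these calls were set side by side.

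The rule for naming genes was set before the data were examined, as were the comparisons, the gene lists and the alternatives except for 1 named below. The genes of the 4 sort antigens were always named. For each pairwise comparison the rule took the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays in the compared populations did not overlap, a separation that chance gives to 10% of genes with 3 arrays against 3. From each gene list with a significant shift, or with at least 3 members past the threshold, it took up to 4 members with the smallest adjusted p. For the interaction it took the 6 largest differences of each sign that were at least as large as the largest range within a population. Predicted genes, olfactory and vomeronasal receptors, small RNAs and segments of antigen receptors were counted but not named. The rule gave 636 pairs of gene and comparison for 321 genes, from which the text takes its examples. Where list members outside the rule are named, they were chosen after their values were seen.

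The 30 gene lists were written from general knowledge. They covered the sort antigens, pericytes and vascular smooth muscle, adventitial fibroblasts, lymphoid stroma, interstitial matrix, basement membrane, chemokines, class I antigen presentation, class II antigen presentation, interferon response, NF-κB targets, retinoid metabolism, growth factors, Wnt signalling, Notch signalling, complement, Hox genes, transcription factors of pharyngeal and cardiac mesenchyme, cell cycle, immediate early genes, T lineage, B cells, myeloid cells, endothelium, epithelium, adipocytes, glia, mesothelium, red blood cells, and genes of the X inactivation centre and the Y chromosome. The lists were tested with camera in limma with a preset correlation of 0.01 between genes, which compares the members of a list with all other genes. The Benjamini-Hochberg method was applied over 174 tests of 29 lists, since 2 measured genes of red blood cells were too few to test. Of the 84 shifts called, 17 were also called when the correlation was estimated from the data. These were pericytes and smooth muscle, adventitial fibroblasts and Wnt signalling between the subsets of both tissues; interstitial matrix between the thymus subsets; pericytes and smooth muscle, lymphoid stroma and Wnt signalling between lymph node PDPN+BP3+ and PDPN- cells; adventitial fibroblasts and lymphoid stroma between lymph node PDPN+BP3+ and PDPN+BP3- cells; Hox genes between the tissues in both subsets; and interstitial matrix, NF-κB targets and epithelium between the tissues in PDPN- cells. Counts of list members are also given adjusted over the list alone, with the Benjamini-Hochberg method applied to its members.

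The alternatives were a fit on the arrays of the compared populations only, a trended and robust prior, genes with low values left out, and every transcript cluster tested. Further alternatives were cyclic loess normalization between arrays, array weights, the replicate number as a fixed block, and the replicate number as a random effect. The last alternatives were a threshold of at least 2-fold and each array left out in turn. For the lists they were cyclic loess, genes with low values left out, an estimated correlation, fry, the replicate block and each array left out in turn. After the data were seen, 1 alternative was added: the genes changed in the same direction in both tissues or both subsets were also counted without thymus PDPN+BP3- replicate 1.

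The procedure was tested on simulated data with 18718 genes of which 200 were changed. It called 28% to 42% of genes changed 1.41-fold, 74% to 96% of those changed 2-fold, 98% to 100% of those changed 4-fold and 100% of those changed 8-fold, and 3.03% to 5.29% of the calls fell on unchanged genes. Without simulated change 0 of 174 list tests were called, and a shifted list was called in 6 of 6 comparisons. The genes were simulated as independent of each other. These list results therefore do not test how the list test behaves when genes of a list are correlated. Each gene had the same spread on all simulated arrays, and the real pairwise comparisons called 1799 to 5337 genes rather than about 200. The shares of recovered genes and of false calls therefore need not hold for the real arrays. No pair of arrays was duplicated, the highest share of equal values between a pair being 2.22%. Files were read with the R package data.table (1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.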

Results

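The 15 arrays separated by podoplanin and then by tissue and BP3. Principal component 1 held 46.5% of the variance and set the 6 PDPN- arrays, at -64.4 to -45.5, apart from the 9 PDPN+ arrays, at 33.4 to 39.3. Component 2 held 25.1% and set the thymus PDPN+BP3- arrays, at 45.6 to 52.9, and the lymph node PDPN+BP3+ arrays, at -55.5 to -52.8, at opposite ends, with lymph node PDPN+BP3- arrays at 3.19 to 10.6. Correlations across genes between arrays of 1 population were 0.987 to 0.995. Between populations their mean was 0.975 for the PDPN- cells of the tissues, 0.967 for the PDPN+BP3- cells of the tissues and 0.960 for lymph node PDPN+BP3+ and PDPN+BP3- cells; genes are not independent replicates. Thymus PDPN+BP3- replicate 1 had an array median of 3.58, against 3.77 to 3.885 on the other arrays.

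**Figure D1:**
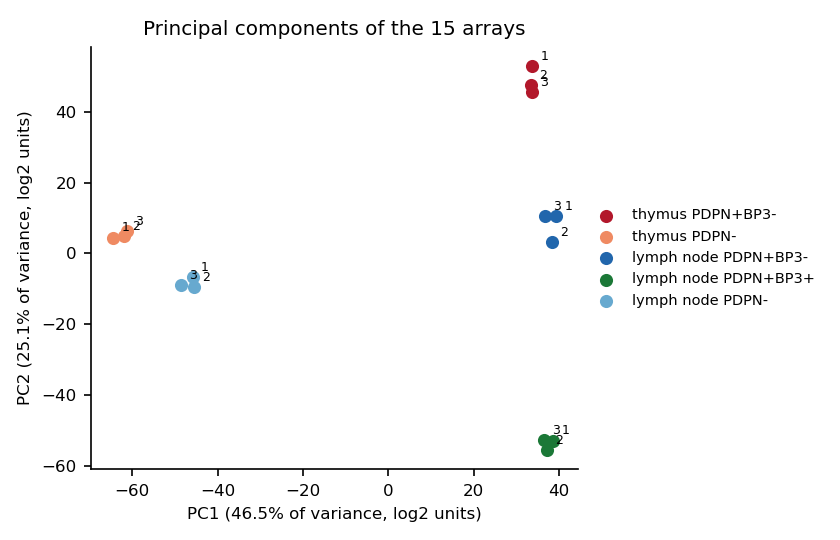
Principal components of the 15 arrays, 1 point per array, with the share of variance on each axis. The 6 PDPN- arrays sit between -64.4 and -45.5 on component 1 and the 9 PDPN+ arrays between 33.4 and 39.3.

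The genes of the sort antigens served as a check of the labels, since the cells were selected on them. Pdpn averaged 9.11 in thymus PDPN+BP3- cells, 8.79 in lymph node PDPN+BP3+ cells and 8.16 in lymph node PDPN+BP3- cells, against 3.01 and 3.41 in the PDPN- cells of thymus and lymph node. Bst1, which encodes BP3, averaged 8.74 in lymph node PDPN+BP3+ cells and 2.18 to 3.30 in the other populations. Enpep, which encodes Ly51, averaged 8.07 and 7.69 in the PDPN- cells of thymus and lymph node and 3.74 to 4.61 elsewhere. Pdgfrb was high in all 5 populations, at 8.94 to 10.61. The arrays of every group lay on the side their labels give.

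**Figure D2:**
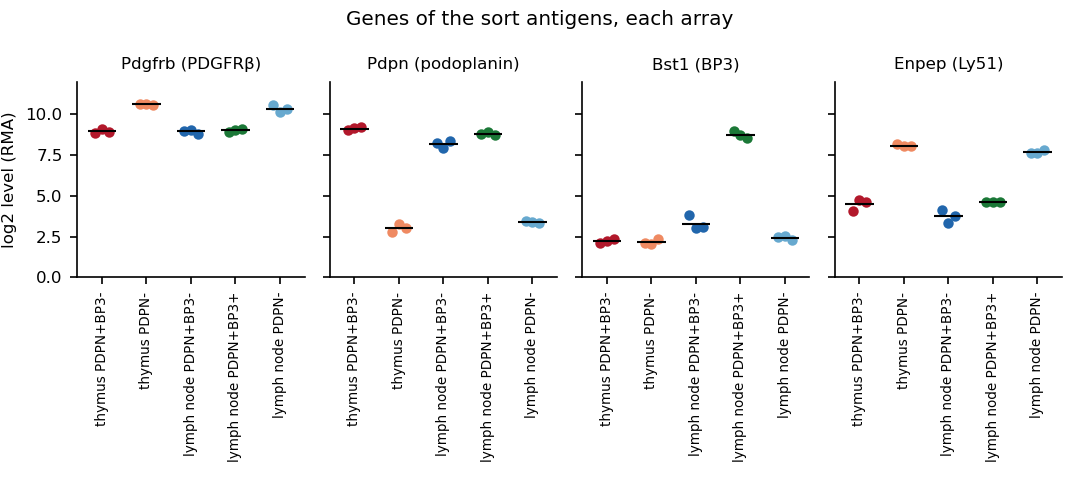
Log2 signal of the 4 sort antigen genes on each array with the mean of 3 arrays per population. Bst1 averages 8.74 in lymph node PDPN+BP3+ cells and at most 3.30 in the other populations.

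How podoplanin-positive and podoplanin-negative mesenchyme of the thymus differ was asked by comparing PDPN+BP3- with PDPN- cells; differences are log2 differences ± the standard error of the limma fit, with n = 3 arrays per population. Genes of adventitial fibroblasts and of interstitial matrix were higher in PDPN+BP3- cells, and genes of pericytes and smooth muscle were higher in PDPN- cells. Pi16, a secreted protein typical of adventitial fibroblasts, was higher in PDPN+BP3- cells (6.64 ± 0.28), and the platelet-derived growth factor receptor Pdgfra (6.44 ± 0.14) and the sialomucin Cd34 (6.38 ± 0.19) were higher too. So were the matrix genes Fndc1 (6.37 ± 0.19), Efemp1 (6.32 ± 0.22), Lum (6.20 ± 0.27) and Vcan (6.07 ± 0.20), the semaphorin Sema3c (5.96 ± 0.20) and the adhesion protein Flrt2 (5.93 ± 0.21). In PDPN- cells the LIM-domain gene Fhl5 was higher (-6.66 ± 0.14), followed by the epoxide hydrolase Ephx3 (-6.14 ± 0.26), the G protein regulator Rgs4 (-6.09 ± 0.23) and the adhesion molecule Esam (-5.74 ± 0.13). The pericyte gene Higd1b (-5.69 ± 0.12), the calcium-store protein Casq2 (-5.60 ± 0.17), the cation channel Trpc6 (-5.30 ± 0.14), the Notch target Nrarp (-5.20 ± 0.12), Pcp4l1 (-5.68 ± 0.18) and the smooth muscle myosin Myh11 (-5.20 ± 0.16) were also higher in PDPN- cells.

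All 25 measured genes of pericytes and smooth muscle were lower in PDPN+BP3- cells (25 adjusted over the list alone; median -3.15), among them Rgs5 (-4.65 ± 0.12) and the integrin Itga7 (-5.09 ± 0.15). The adjusted p was 2.01e-29 by camera and 0.00127 with an estimated correlation. Of 18 adventitial fibroblast genes 17 were higher (17 adjusted over the list alone; median 4.94, adjusted p 6.10e-26). Among them were the alarmin Il33 (5.57 ± 0.12) and Igfbp6 (5.50 ± 0.16). Of 24 interstitial matrix genes 23 were higher (23 adjusted over the list alone; median 1.47, adjusted p 6.20e-25). These included Fbln2 (5.78 ± 0.16), Fbln1 (4.52 ± 0.15), the cross-linking enzyme Loxl1 (4.25 ± 0.16) and Col1a1 (3.21 ± 0.13). Wnt signalling genes were higher in 14 of 20 cases (16 higher and 1 lower adjusted over the list alone; median 1.54, adjusted p 1.75e-14). Examples were the secreted Wnt antagonists Sfrp2 (5.87 ± 0.11), Sfrp4 (5.84 ± 0.19), Sfrp1 (5.03 ± 0.15) and Dkk2 (4.73 ± 0.24).

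Notch signalling genes were lower in PDPN+BP3- thymus cells in 8 of 13 cases (9 adjusted over the list alone; median -1.67, adjusted p 1.98e-06, adjusted p = 0.0574 with an estimated correlation). Among them were Notch3 (-3.46 ± 0.19), the effector Heyl (-2.82 ± 0.16) and the ligand Jag1 (-2.22 ± 0.12). Of 19 growth factor genes 11 were higher, such as Fgf10 (5.26 ± 0.11) and the lymphangiogenic factor Vegfc (3.81 ± 0.15), and 7 lower, such as Bmp5 (-3.11 ± 0.14), the same counts adjusted over the list alone (median 1.27, adjusted p 0.00163, adjusted p = 0.218 with an estimated correlation). Lymphoid stroma genes were higher in 7 of 18 cases and lower in 1 (8 and 1 adjusted over the list alone; median 0.34, adjusted p 3.90e-05, adjusted p = 0.0677 with an estimated correlation). The median was 0.51 without thymus PDPN+BP3- replicate 1 and 0.19 without replicate 3. The B cell chemokine Cxcl13 stood at 4.44 ± 0.23 and the cytokine Tnfsf13b at 2.15 ± 0.16. Of 19 chemokine genes 9 were higher and 2 lower (9 and 4 adjusted over the list alone; median 0.11, adjusted p 4.46e-04, adjusted p = 0.183 with an estimated correlation). Their median was 0.36 without thymus PDPN+BP3- replicate 1, 0.07 without replicate 3, and 0.41 and 0.25 without thymus PDPN- replicates 2 and 3. These included Ccl7 (3.76 ± 0.23), Cx3cl1 (3.25 ± 0.16) and Cxcl14 (3.05 ± 0.10). The retinaldehyde dehydrogenases Aldh1a1 (3.77 ± 0.24) and Aldh1a3 (2.27 ± 0.17) were among 7 of 14 retinoid genes that were higher (7 adjusted over the list alone; median 0.32, adjusted p 1.18e-04, adjusted p = 0.0677 with an estimated correlation). Of 7 mesothelium genes 4 were higher (5 adjusted over the list alone; median 0.51, adjusted p 6.15e-04, adjusted p = 0.0657 with an estimated correlation). The transcription factor Wt1 stood at 3.09 ± 0.13. Only 1 of the 7 exceeded the median of the table in a thymus population, so most of this shift lies among low signals.

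In this comparison 5337 genes passed an adjusted p of 0.05, 1922 higher and 3415 lower in PDPN+BP3- cells. The share of lower calls, 64.0%, was 44.5% after cyclic loess (2711 higher and 2178 lower) and 52.5% without thymus PDPN+BP3- replicate 1 (2120 higher and 2343 lower). Fewer thymocyte and epithelium genes were called without the same array. Cd3d, a subunit of the T cell receptor complex, was lower in PDPN+BP3- cells (-1.21 ± 0.40). Its difference was -0.46 without that array, still past the threshold, and it did not pass without thymus PDPN- replicate 2 (-1.23) or 3 (-1.08), in a fit on the arrays of the thymus subsets only (adjusted p 0.139) or with a trended and robust prior (adjusted p 0.0701; 0.00687 to 0.139 over its alternatives). Of 13 T lineage genes 4 were lower (7 adjusted over the list alone; median -0.73, adjusted p 0.0593), and 2 were lower and 1 higher without the array (median -0.26, adjusted p 0.210). Of 14 epithelium genes 7 were lower (9 lower and 1 higher adjusted over the list alone; median -0.51, adjusted p 0.0566), and 1 was lower and 1 higher without the array (median -0.33, adjusted p 0.154). Of 8 genes of class II antigen presentation 4 were lower (5 adjusted over the list alone; median -0.96, adjusted p 0.0741), and 2 were lower without the array (median -0.51, adjusted p 0.140). The mean of the T lineage genes was 3.19 on replicate 1 and 4.39 and 4.51 on the other PDPN+BP3- arrays, against 4.50 to 5.02 on the PDPN- arrays.

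The same comparison in lymph node asked how PDPN+BP3- and PDPN- cells differ there. The angiotensin receptor Agtr2 was higher in PDPN+BP3- cells (7.01 ± 0.21), as were the methyltransferase Inmt (6.60 ± 0.29), the tight-junction claudin Cldn1 (6.51 ± 0.18), the matrix protein Tgfbi (5.63 ± 0.17) and the transcription factor Osr1 (5.61 ± 0.19). The dipeptidase Dpep1 (5.51 ± 0.25), the monooxygenase Fmo2 (5.35 ± 0.27), Il33 (5.31 ± 0.12), Pdgfra (5.18 ± 0.14) and Shisa3 (5.13 ± 0.16) followed. Higher in PDPN- cells were Fhl5 (-6.24 ± 0.14), Fam162b (-5.78 ± 0.19), Rgs4 (-5.49 ± 0.23), the cGMP-dependent kinase Prkg2 (-5.30 ± 0.18), the endothelin receptor Ednrb (-5.09 ± 0.14) and Nrarp (-4.99 ± 0.12). Stac (-4.88 ± 0.13), Map3k7cl (-4.73 ± 0.13), the tetraspanin Tspan15 (-4.70 ± 0.18) and Chn1 (-4.66 ± 0.18) were higher there too.

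Of 25 pericyte and smooth muscle genes 23 were lower in lymph node PDPN+BP3- cells (24 adjusted over the list alone; median -2.27, adjusted p 1.42e-28). Among them were Higd1b (-4.22 ± 0.12), Myh11 (-3.98 ± 0.16) and the smooth muscle coactivator Myocd (-3.34 ± 0.13). Adventitial fibroblast genes were higher in 15 of 18 cases (15 higher and 1 lower adjusted over the list alone; median 2.52, adjusted p 3.45e-16). These included Cd34 (5.05 ± 0.19), Clec3b (4.24 ± 0.23) and Igfbp6 (4.07 ± 0.16). Of 20 Wnt signalling genes 12 were higher (12 adjusted over the list alone; median 1.63, adjusted p 4.24e-12). Examples were Sfrp2 (4.98 ± 0.11), Wnt2b (3.34 ± 0.20) and Wnt5a (3.31 ± 0.17). Interstitial matrix genes were higher in 16 of 24 cases and lower in 1 (17 and 1 adjusted over the list alone; median 0.995, adjusted p 1.49e-10, adjusted p = 0.0657 with an estimated correlation). Among them were Fbln5 (4.50 ± 0.19) and Fbln2 (4.42 ± 0.16). Of 18 lymphoid stroma genes 11 were higher and 1 lower, the same counts adjusted over the list alone (median 1.17, adjusted p 2.03e-06, adjusted p = 0.0507 with an estimated correlation). They included Cxcl13 (4.68 ± 0.23), the BMP antagonist Grem1 (4.30 ± 0.12), Tnfsf13b (2.93 ± 0.16) and the chemokine Cxcl12 (2.81 ± 0.14).

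Cell cycle genes were lower in lymph node PDPN+BP3- cells in 14 of 22 cases (16 adjusted over the list alone; median -0.91, adjusted p 7.07e-09, adjusted p = 0.231 with an estimated correlation). These included the mitotic kinase Bub1 (-1.82 ± 0.20) and Mki67 (-1.57 ± 0.22). Notch signalling genes were lower in 8 of 13 cases and higher in 2 (8 and 2 adjusted over the list alone; median -0.62, adjusted p 2.57e-04, adjusted p = 0.121 with an estimated correlation). Hey2 stood at -2.77 ± 0.20 and Notch3 at -2.27 ± 0.19. Of 19 interferon response genes 7 were lower and 1 higher (10 and 2 adjusted over the list alone; median -0.36, adjusted p 0.00333, adjusted p = 0.419 with an estimated correlation). Oas1a stood at -2.38 ± 0.31 and Irf7 at -1.27 ± 0.17. The endothelial genes Tek (2.71 ± 0.19), a receptor, and Cdh5 (2.15 ± 0.19), a cadherin, were higher in PDPN+BP3- cells, and Esam was lower (-4.54 ± 0.13). In all 4332 genes passed, 2500 higher and 1832 lower in PDPN+BP3- cells.

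The subset comparisons of thymus and lymph node share no array, and 2436 genes passed in both with the same sign. Of these, 1206 were higher in PDPN+BP3- cells, where independent calls would share 257, and 1230 were lower, where they would share 334. Opposite signs were found for 187 genes, where 644 would be shared. Il33, Pdgfra, Cd34, Sfrp2 and Cxcl13 were higher and Fhl5, Rgs4, Nrarp, Higd1b and Myh11 lower in PDPN+BP3- cells of both tissues. Across genes the differences in the tissues had a Pearson correlation of 0.714 and a Spearman correlation of 0.464; genes are not independent replicates.

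How the BP3+ cells of the lymph node differ from PDPN- cells was asked next. The desmosomal cadherins Dsc3 (7.76 ± 0.13, over a mean of 2.39 in PDPN- cells) and Dsc2 (6.72 ± 0.15) were higher in PDPN+BP3+ cells, as were the cystine transporter Slc7a11 (6.85 ± 0.20), Il33 (6.62 ± 0.12), Grem1 (6.60 ± 0.12) and Cxcl13 (6.52 ± 0.23). The microtubule regulator Stmn2 (6.5 ± 0.16), Shisa3 (6.49 ± 0.16) and the sort antigen gene Bst1 (6.32 ± 0.18, over a mean of 2.41) followed. Csf2rb2 was higher as well (6.57 ± 0.30), but its signal is not separable with certainty from that of its close paralog. Higher in PDPN- cells were the carboxypeptidase Cpe (-6.11 ± 0.14), the matrix genes Sparcl1 (-6.04 ± 0.14), Lama2 (-5.37 ± 0.16) and Mfap5 (-5.26 ± 0.20), the lipid carrier Fabp4 (-5.59 ± 0.25), Esam (-5.27 ± 0.13) and Ednrb (-5.16 ± 0.14). Adap2 (-5.12 ± 0.17), Art3 (-5.11 ± 0.15) and the lipid phosphatase Inpp4b (-5.07 ± 0.13) were higher there too.

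Of 18 lymphoid stroma genes 13 were higher in PDPN+BP3+ than in PDPN- cells (13 adjusted over the list alone; median 2.51, adjusted p 2.77e-14). Examples were the cytokines Tnfsf13b (4.55 ± 0.16) and Il7 (4.38 ± 0.17). Pericyte and smooth muscle genes were lower in 22 of 25 cases and higher in 2 (23 and 2 adjusted over the list alone; median -1.82, adjusted p 3.19e-19). Itga7 stood at -4.70 ± 0.15 and the calponin Cnn1 at -4.41 ± 0.21. Wnt signalling genes were higher in 11 of 20 cases and lower in 1 (11 and 1 adjusted over the list alone; median 0.62, adjusted p 3.26e-06). Among them were Sfrp2 (5.44 ± 0.11) and Rspo3 (2.51 ± 0.17). Cell cycle genes were higher in 19 of 22 cases (19 adjusted over the list alone; median 0.90, adjusted p 1.58e-07, adjusted p = 0.279 with an estimated correlation). Without PDPN+BP3+ replicate 2, 12 of them passed. Tpx2 stood at 1.97 ± 0.14 and Mcm2 at 1.18 ± 0.17. Of 19 interferon response genes 13 were lower and 1 higher (13 and 1 adjusted over the list alone; median -0.73, adjusted p 1.14e-06, adjusted p = 0.183 with an estimated correlation). These included Rtp4 (-2.68 ± 0.16) and Ifit1 (-2.24 ± 0.14). Basement membrane genes were lower in 10 of 15 cases (11 adjusted over the list alone; median -0.60, adjusted p 2.72e-06, adjusted p = 0.177 with an estimated correlation). Immediate early genes were lower in 9 of 14 cases (9 adjusted over the list alone; median -0.45, adjusted p 6.24e-04, adjusted p = 0.316 with an estimated correlation). Atf3 stood at -0.70 ± 0.13. For interstitial matrix the median was -0.02 but the mean 0.45, with 9 genes higher and 4 lower (10 and 5 adjusted over the list alone) and an adjusted p of 0.179 for a shift upward. In all 5118 genes passed, 3013 higher and 2105 lower.

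Within the podoplanin-positive cells of the lymph node, PDPN+BP3+ were compared with PDPN+BP3- cells to ask what goes with BP3. Slc7a11 (6.35 ± 0.20), Stmn2 (5.94 ± 0.16), the sort antigen gene Bst1 (5.44 ± 0.18), the matrix protein Thbs4 (5.31 ± 0.26), Dsc2 (4.89 ± 0.15) and the phosphatidylserine receptor Timd4 (4.87 ± 0.18) were higher in PDPN+BP3+ cells. The lipid carrier Fabp7 (4.6 ± 0.15), the secreted hormone Stc2 (4.43 ± 0.15), the retinol acyltransferase Lrat (4.41 ± 0.19) and the phospholipase Pla2g5 (4.39 ± 0.14) followed. The microfibril gene Mfap5 was higher in PDPN+BP3- cells (-7.48 ± 0.20), followed by the glypican Gpc3 (-6.47 ± 0.15), the opioid precursor Penk (-6.24 ± 0.20), Inmt (-6.21 ± 0.29), Cpe (-5.86 ± 0.14) and Lama2 (-5.80 ± 0.16). Cd34 (-5.72 ± 0.19), Efemp1 (-5.52 ± 0.22), the zinc finger gene Zim1 (-5.48 ± 0.17) and Itm2a (-5.38 ± 0.20) were also higher in PDPN+BP3- cells.

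Of 18 adventitial fibroblast genes 14 were lower in PDPN+BP3+ cells and 1, Il33, was higher (15 and 1 adjusted over the list alone; median -2.49, adjusted p 1.13e-19). Igfbp6 stood at -5.07 ± 0.16 and Sema3c at -4.44 ± 0.20. Lymphoid stroma genes were higher in 11 of 18 cases (14 higher and 1 lower adjusted over the list alone; median 0.90, adjusted p 1.49e-10). Among them were the addressin Madcam1 (3.95 ± 0.25), the hydroxylase Ch25h (3.77 ± 0.25), Il7 (2.97 ± 0.17) and Grem1 (2.30 ± 0.12). Cell cycle genes were higher in 21 of 22 cases (21 adjusted over the list alone; median 1.72, adjusted p 3.25e-23, adjusted p = 0.0657 with an estimated correlation). These included Tpx2 (3.30 ± 0.14), Bub1 (2.49 ± 0.20) and Top2a (2.37 ± 0.19). Interstitial matrix genes were lower in 17 of 24 cases and higher in 2 (19 and 3 adjusted over the list alone; median -0.89, adjusted p 4.89e-12, adjusted p = 0.0539 with an estimated correlation). Lum stood at -3.88 ± 0.27 and Fbln1 at -2.65 ± 0.15.

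NF-κB targets were higher in PDPN+BP3+ cells in 10 of 17 cases and lower in 2 (10 and 2 adjusted over the list alone; median 0.71, adjusted p 3.40e-04, adjusted p = 0.288 with an estimated correlation). Examples were Bcl3 (1.36 ± 0.13) and Nfkb2 (1.10 ± 0.16), while the cytokine Il6 was lower (-2.98 ± 0.31). Of 19 growth factor genes 8 were lower and 5 higher (10 and 6 adjusted over the list alone; median -0.41, adjusted p 3.02e-04, adjusted p = 0.179 with an estimated correlation). Among them were Gdf10 (-5.09 ± 0.14), Igf2 (-4.54 ± 0.17), Fgf10 (-3.98 ± 0.11) and Fgf7 (-3.65 ± 0.25), all lower. Wnt signalling genes were lower in 8 of 20 cases and higher in 4 (8 and 4 adjusted over the list alone; median -0.23, adjusted p 0.00271, adjusted p = 0.127 with an estimated correlation). Sfrp4 stood at -4.33 ± 0.19. Endothelium genes were lower in 10 of 19 cases and higher in 2 (12 and 2 adjusted over the list alone; median -0.65, adjusted p 1.01e-04, adjusted p = 0.183 with an estimated correlation). Tek stood at -1.86 ± 0.19 and Cdh5 at -1.78 ± 0.19. Interferon response genes were lower in 10 of 19 cases and higher in 2 (12 and 2 adjusted over the list alone; median -0.55, adjusted p 1.41e-04, adjusted p = 0.279 with an estimated correlation). The retinoic acid hydroxylase Cyp26b1 was higher (3.35 ± 0.13). In all 3038 genes passed, 1589 higher and 1449 lower in PDPN+BP3+ cells.

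**Figure D3:**
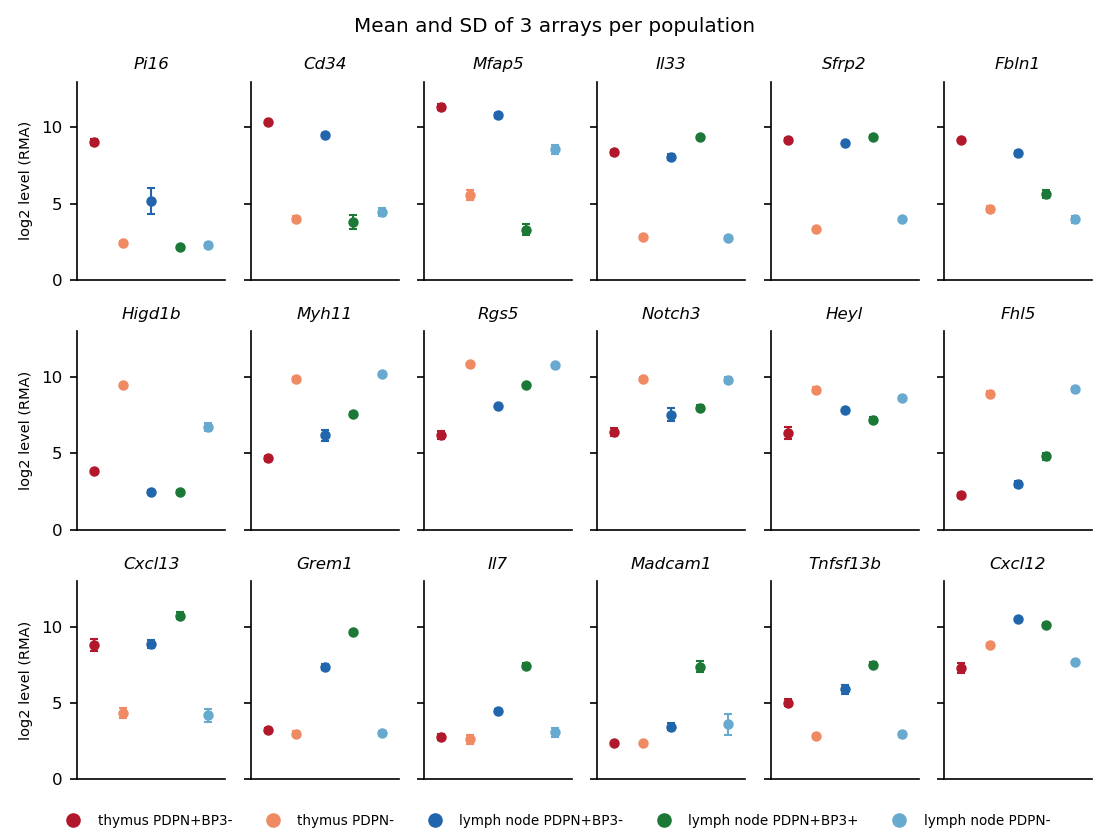
Mean log2 signal and standard deviation of 3 arrays per population for 18 genes, grouped as higher in PDPN+BP3- cells, higher in PDPN- cells and lymphoid stroma. Between PDPN+BP3- and PDPN- cells of the thymus Pi16 differs by 6.64 and Higd1b by -5.69, and between PDPN+BP3+ and PDPN+BP3- cells of the lymph node Madcam1 differs by 3.95.

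How the PDPN+BP3- subset differs between the tissues was asked by comparing these cells of lymph node with those of thymus. Glycam1, a mucin-like ligand of L-selectin, was higher in lymph node (7.03 ± 0.91, over a mean of 2.85 in thymus), as were Cldn1 (6.12 ± 0.18), the BMP antagonists Chrdl1 (5.04 ± 0.21) and Grem1 (4.11 ± 0.12), the angiopoietin Angpt2 (4.76 ± 0.17) and the chloride channel Ano1 (4.39 ± 0.18). Gabrg3 (4.63 ± 0.20), Gdpd2 (4.56 ± 0.14), Agtr2 (3.73 ± 0.21) and the secretogranin Scg3 (3.72 ± 0.33) were higher there too. Higher in thymus were Cpxm2 (-5.23 ± 0.23), the receptor tyrosine kinase Ret (-4.87 ± 0.14), the glucocorticoid-activating enzyme Hsd11b1 (-4.82 ± 0.29), the transcription factor Tcf21 (-4.71 ± 0.17), the prostacyclin synthase Ptgis (-4.48 ± 0.20) and Bmp4 (-4.41 ± 0.22). Pla1a (-4.39 ± 0.18), the complement protease Masp1 (-4.31 ± 0.11), the guidance cue Slit2 (-4.30 ± 0.27) and Tnfrsf19 (-4.28 ± 0.14) were also higher in thymus.

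Of 29 Hox genes 18 were higher in lymph node PDPN+BP3- cells and 2 lower (19 and 2 adjusted over the list alone; median 0.94, adjusted p 6.68e-09, 0.0102 with an estimated correlation). Examples were Hoxc8 (3.38 ± 0.21), Hoxc6 (3.35 ± 0.19) and Hoxd9 (2.74 ± 0.19). T lineage genes were lower in 10 of 13 cases (12 adjusted over the list alone; median -1.55, adjusted p 3.01e-09, adjusted p = 0.152 with an estimated correlation). Among them were Cd8a (-2.53 ± 0.42, and -3.25 without thymus PDPN+BP3- replicate 1) and Dntt (-2.20 ± 0.31). Epithelium genes were lower in 10 of 14 cases (12 adjusted over the list alone; median -0.66, adjusted p 3.33e-10, adjusted p = 0.0879 with an estimated correlation). The keratin Krt18 stood at -3.72 ± 0.35 and the thymic protease Prss16 at -2.37 ± 0.33. Class II antigen presentation genes were lower in 5 of 8 cases (5 lower and 1 higher adjusted over the list alone; median -0.93, adjusted p 3.10e-04, adjusted p = 0.218 with an estimated correlation). Without thymus PDPN+BP3- replicate 3, 3 were lower and 1 higher. H2-Aa stood at -2.59 ± 0.35 and Cd74 at -2.55 ± 0.30. Endothelium genes were higher in lymph node in 11 of 19 cases (14 adjusted over the list alone; median 0.54, adjusted p 1.20e-07, adjusted p = 0.0828 with an estimated correlation). These included Cdh5 (2.52 ± 0.19) and Sox18 (1.96 ± 0.18).

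Lymphoid stroma genes were higher in lymph node PDPN+BP3- cells in 12 of 18 cases and lower in 2 (12 and 3 adjusted over the list alone; median 0.98, adjusted p 4.50e-05, adjusted p = 0.0677 with an estimated correlation). Cxcl12 stood at 3.19 ± 0.14 and the cytokine Il15 at -2.63 ± 0.16. Pericyte and smooth muscle genes were higher in 15 of 25 cases and lower in 5 (15 and 5 adjusted over the list alone; median 0.81, adjusted p 2.63e-05, adjusted p = 0.0677 with an estimated correlation). Examples were the guanylate cyclase Gucy1a1 (2.60 ± 0.14) and Rgs5 (1.86 ± 0.12). Adventitial fibroblast genes were lower in 8 of 18 cases and higher in 1 (11 and 1 adjusted over the list alone; median -0.44, adjusted p 5.07e-08, adjusted p = 0.0879 with an estimated correlation). Pi16 stood at -3.89 ± 0.28. Immediate early genes were higher in 11 of 14 cases (13 adjusted over the list alone; median 0.49, adjusted p 7.84e-06, adjusted p = 0.201 with an estimated correlation). The number higher was 7 without thymus replicate 1 or lymph node replicate 1 and 6 without lymph node replicate 2. The nuclear receptor Nr4a1 stood at 2.11 ± 0.23. Transcription factors of pharyngeal and cardiac mesenchyme were lower in 12 of 29 cases and higher in 2 (13 and 2 adjusted over the list alone; median -0.12, adjusted p 1.26e-04, adjusted p = 0.0677 with an estimated correlation). The median was -0.19 without thymus replicate 1 or 2, -0.21 without lymph node replicate 2 and -0.20 without lymph node replicate 3. Hand2 stood at -1.77 ± 0.16 and Foxf1 at 2.17 ± 0.20. The mesothelium gene Wt1 was lower (-3.09 ± 0.13), as were the chemokines Cxcl14 (-3.27 ± 0.10) and Cx3cl1 (-2.89 ± 0.16). In all 3205 genes passed, 2215 higher and 990 lower in lymph node, a share of lower calls of 30.9% that was 53.9% after cyclic loess (1343 higher and 1573 lower) and 45.4% without thymus PDPN+BP3- replicate 1 (1381 higher and 1150 lower).

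The PDPN- cells of lymph node and thymus were compared to ask how the podoplanin-negative subset differs between the tissues. Fam162b was higher in lymph node (6.40 ± 0.19), as were the transcription factors Meox1 (4.57 ± 0.18) and Hoxc6 (4.18 ± 0.19) and the matrix genes Fndc1 (4.26 ± 0.19) and Dpt (3.73 ± 0.27). Pamr1 (3.62 ± 0.15) and the serpins Serpina1b (5.29 ± 0.38) and Serpina1d (4.54 ± 0.17) were higher too, as was H2-M9 (3.6 ± 0.17). The serpins are near-identical paralogs and H2-M9 has close relatives, so their signals are not separable with certainty. Glycam1 was higher in lymph node (4.56 ± 0.91) but stood at 8.85, 9.43 and 3.86 on the 3 lymph node arrays, and its difference was 6.32 without lymph node PDPN- replicate 3, 3.54 without replicate 2 and 3.83 without replicate 1. Higher in thymus were the class II antigen presentation genes H2-Aa (-5.22 ± 0.35) and Cd74 (-4.56 ± 0.30), the T cell precursor chemokine Ccl25 (-5.14 ± 0.40), Krt18 (-4.64 ± 0.35), the lectin Reg3g (-4.03 ± 0.29), Tbata (-3.66 ± 0.31), the leukocyte genes Cd52 (-3.66 ± 0.34) and Laptm5 (-3.51 ± 0.32), and Cd8a (-3.47 ± 0.42). Another transcript cluster of Ccl25 differed in the opposite direction at an unadjusted p under 0.05 in limma. The transcription factor Tcf21 was higher in thymus in this subset too (-4.02 ± 0.17).

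Of 29 Hox genes 16 were higher in lymph node PDPN- cells and 1 lower (18 and 3 adjusted over the list alone; median 0.97, adjusted p 8.83e-15, 0.00311 with an estimated correlation). Hoxc8 stood at 3.55 ± 0.21 and Hoxc9 at 2.62 ± 0.19. NF-κB targets were higher in 14 of 17 cases (16 adjusted over the list alone; median 0.79, adjusted p 3.10e-15). Examples were the adhesion molecules Vcam1 (2.51 ± 0.13) and Icam1 (1.42 ± 0.20) and the inhibitor Tnfaip3 (1.25 ± 0.20). Interstitial matrix genes were higher in 13 of 24 cases and lower in 1 (15 and 1 adjusted over the list alone; median 0.61, adjusted p 3.37e-13). Among them were Col1a1 (2.25 ± 0.13), Dcn (1.94 ± 0.15) and Tnc (1.84 ± 0.14). Epithelium genes were lower in 11 of 14 cases (14 adjusted over the list alone; median -1.21, adjusted p 3.45e-16). Krt8 stood at -3.31 ± 0.34 and Prss16 at -3.01 ± 0.33. T lineage genes were lower in 11 of 13 cases (12 adjusted over the list alone; median -2.35, adjusted p 1.40e-15, adjusted p = 0.0657 with an estimated correlation). Cd3g stood at -3.05 ± 0.37 and Dntt at -2.97 ± 0.31. Class II antigen presentation genes were lower in 5 of 8 cases (7 adjusted over the list alone; median -1.29, adjusted p 1.38e-08, adjusted p = 0.0706 with an estimated correlation).

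Adventitial fibroblast genes were higher in lymph node PDPN- cells in 7 of 18 cases (10 higher and 1 lower adjusted over the list alone; median 0.59, adjusted p 1.95e-05, adjusted p = 0.179 with an estimated correlation). These included Dpt and Mfap5 (2.99 ± 0.20). Class I antigen presentation genes were higher in 4 of 12 cases (6 adjusted over the list alone; median 0.30, adjusted p 6.51e-05, adjusted p = 0.183 with an estimated correlation). H2-K1 stood at 0.96 ± 0.11 and Psmb9 at 0.84 ± 0.15. The pericyte gene Higd1b was lower in lymph node (-2.80 ± 0.12), and pericyte and smooth muscle genes were lower in 8 of 25 cases and higher in 2 (8 and 2 adjusted over the list alone; median -0.26, adjusted p 0.0101, adjusted p = 0.222 with an estimated correlation). The Wnt effector Lef1 (-2.08 ± 0.26) and the factor Bmp4 (-1.47 ± 0.22) were lower, and the complement genes C2 (1.62 ± 0.14) and Cfb (1.59 ± 0.14) were higher. In all 1799 genes passed, 827 higher and 972 lower in lymph node.

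**Figure D4:**
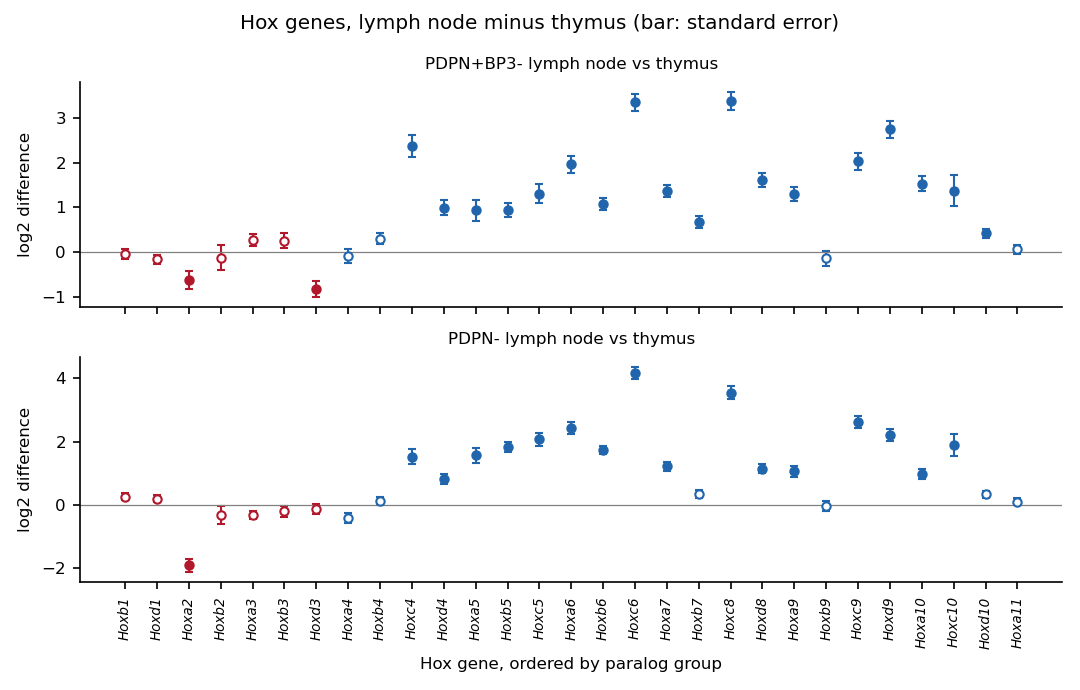
Log2 difference of lymph node minus thymus for 29 Hox genes by paralog group, with the standard error of the fit, for PDPN+BP3- and PDPN- cells; filled points passed an adjusted p of 0.05. Members of groups 4 to 11 average 1.34 and 1.42 in PDPN+BP3- and PDPN- cells, and members of groups 1 to 3 average -0.19 and -0.36.

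The tissue comparisons of the subsets share no array, and 593 genes passed in both with the same sign. Of these, 355 were higher in lymph node, where independent calls would share 97.9, and 238 were higher in thymus, where they would share 51.4. Opposite signs were found for 200 genes, where 159 would be shared. These comparisons also use 1 spread per gene from all 15 arrays, so their calls are not fully independent. Hoxc6, Hoxc8, Vcam1 and Foxf1 were higher in lymph node in both subsets, and Tcf21, Bmp4, Col15a1, Krt18 and Cd74 were higher in thymus in both. Across genes the Pearson correlation of the differences was 0.247 and the Spearman correlation 0.0914. The interaction, which asks whether the subset difference depends on the tissue, passed for 2381 genes, 1623 with a higher and 758 with a lower difference in lymph node. That share of lower differences, 31.8%, was 57.8% after cyclic loess (871 higher and 1193 lower) and 44.5% without thymus PDPN+BP3- replicate 1 (1146 higher and 918 lower).

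**Figure D5:**
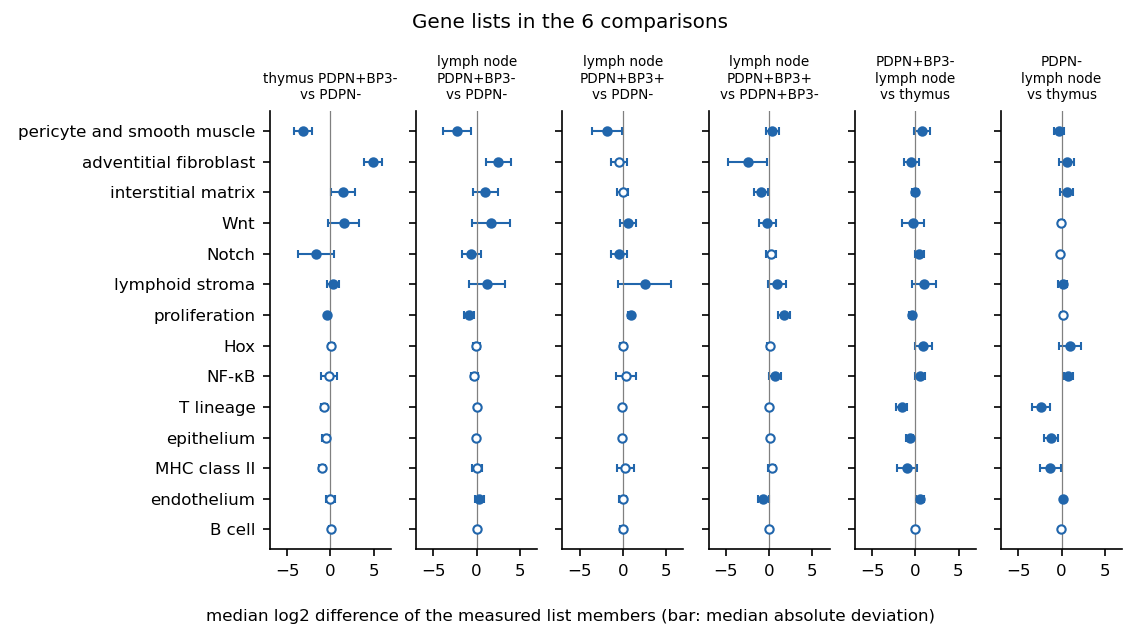
Median log2 difference and median absolute deviation of 14 gene lists in 6 comparisons; filled points had an adjusted p under 0.05 by camera with the preset correlation. Pericyte and smooth muscle genes have medians of -3.15, -2.27 and -1.82 in PDPN+BP3- thymus, PDPN+BP3- lymph node and PDPN+BP3+ lymph node cells against PDPN- cells.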

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

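The tests of the 3 patterns weighed here (T lineage and epithelium genes, the balance of calls between the thymus subsets, and Hox genes) were all chosen after the results were seen, as was the exchange of residuals for the interaction, while the interaction and the counts over other splits of the arrays had been set earlier.

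The difference between PDPN+BP3- and PDPN- cells differed between lymph node and thymus for 2381 genes, which is what set these genes apart for a closer look. Among them, 606 passed in both tissues with the same sign, 187 passed in both with opposite signs, 889 passed in thymus only, 627 in lymph node only and 72 in neither. The largest positive interactions, lymph node minus thymus, were those of the claudin Cldn1 (5.93 ± 0.25), Ddit4l (5.90 ± 0.38), the leptin receptor Lepr (5.41 ± 0.26), Shisa6 (4.94 ± 0.32), the chloride channel Ano1 (4.93 ± 0.26) and the angiopoietin Angpt2 (4.52 ± 0.25). The largest negative interactions were those of the transcription factor Meox1 (-6.74 ± 0.26), Cpxm2 (-6.11 ± 0.33), the kinase Prkg2 (-5.93 ± 0.25), Fam162b (-5.73 ± 0.27), the matrix gene Fndc1 (-5.69 ± 0.27) and the receptor Ret (-5.02 ± 0.20). Meox1 averaged 7.29 in PDPN+BP3- and 3.17 in PDPN- cells of the thymus, but 5.11 and 7.74 in those of the lymph node. Lepr averaged 5.80 and 6.23 in these thymus cells and 8.63 and 3.65 in the lymph node cells. Under cyclic loess 2064 genes passed, of which 1609 were also among the 2381.

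Of 100 splits of the tissue labels within the subsets, 2 gave as many interaction genes as the 2381 of the real one, the real one included. Splits that mix the tissues move their difference into the residual spread, so these counts do not test the interaction alone. The highest other value, 2995, came from exchanging the tissues in 1 subset only. That split measures the sum of the tissue differences rather than their difference, and the highest of the remaining splits gave 1305. The residuals of an additive fit of tissue and subset were also exchanged between the 12 arrays. Of 100 orders 1, the real one, gave as many genes, and the highest other gave 1007. The share of 0.01 is the smallest that 100 orders allow, and it bears only on whether any gene has an interaction. Exchanges move the interaction itself into the spread within populations, so they do not show how many of the 2381 calls are due to chance. They also treat the arrays as alike in spread, though the values of thymus PDPN+BP3- replicate 1 were compressed. For each pairwise comparison the 6 arrays allow 10 splits, too few for a share under 0.05. In each of them 1 of the 10 splits, the real one, gave as many genes as the real one. Here too the other splits mix the populations and move their difference into the residual spread. Low counts from these splits follow from that and do not bear on chance. For the thymus subsets the real split gave 5337 genes and the highest other 0. For the lymph node the values were 4332 and 1 for PDPN+BP3- against PDPN- cells, 5118 and 0 for PDPN+BP3+ against PDPN- cells, and 3038 and 0 for PDPN+BP3+ against PDPN+BP3- cells. Between the tissues they were 3205 and 2 in PDPN+BP3- cells and 1799 and 1 in PDPN- cells.

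T lineage and epithelium genes were higher in thymus than in lymph node in both subsets with the preset correlation, but with an estimated correlation only epithelium in PDPN- cells passed (adjusted p = 0.0473, against 0.0879 in PDPN+BP3- cells and, for T lineage, 0.152 in PDPN+BP3- and 0.0657 in PDPN- cells). Normalization between arrays is argued against as the whole cause, since at least 98.6% of the median differences of both lists were left after cyclic loess. RNA of thymocytes and thymic epithelium in the sorts and expression by thymic mesenchyme itself, a tissue difference the design names, cannot be told apart, since either would give the pattern: at least 71.4% of the members of either list passed as higher in thymus in either subset. Levels of abundant members were 6.52 and 7.65 for Krt18 and 5.94 and 7.04 for Cd8a in PDPN+BP3- and PDPN- thymus cells, no other list held any of their genes, and 0 of 13 T lineage and 1 of 14 epithelium genes exceeded the median of the table in any lymph node population. The sorts were gated as PDGFRβ-positive, their purity was not examined here, and neither explanation was tested apart from the other.

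Lower calls outnumbered higher ones in thymus PDPN+BP3- against PDPN- cells, at 64.0%. Without thymus PDPN+BP3- replicate 1, whose values were compressed (median 3.58 and upper quartile 5.64, against upper quartiles of 6.07 to 6.22 on the other arrays), the share was 52.5%, and without any of the other 5 arrays it was at least 61.4%. The compressed values of this array are a candidate explanation of part of the imbalance. After cyclic loess the share was 44.5%, but cyclic loess centres the differences between arrays and so evens the calls by construction, which leaves level distributions of the arrays in general open. A biological imbalance between the subsets was not tested.

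Hox genes were higher in the lymph node populations than in those of the thymus. Normalization is argued against as the whole cause, since at least 86.7% of the median difference was left after cyclic loess. Whether RNA of endothelial cells in the lymph node sorts, which were gated as PDGFRβ-positive, adds to the difference stays open. Array means of the Hox list were 4.44 to 4.49 in lymph node PDPN+BP3+ cells. They were 3.43 to 3.48 in thymus PDPN- cells and 3.34 to 3.57 in thymus PDPN+BP3- cells. Those of the endothelium list were 3.48 to 3.62, 3.50 to 3.63 and 3.13 to 3.21 in the same order. The endothelium list was thus level with 1 thymus population and higher than the other, and PDPN+BP3+ cells have no thymus counterpart here. In PDPN+BP3- and PDPN- cells the endothelium list was higher in lymph node than in thymus too (medians 0.54 and 0.22). Between PDPN+BP3+ and PDPN+BP3- cells the endothelium list had a median of -0.65 (median absolute deviation 0.598, adjusted p 1.01e-04, adjusted p = 0.183 with an estimated correlation). The 18 Hox genes higher in lymph node PDPN+BP3- cells had a median of 0.0617 there (median absolute deviation 0.544), and PDPN- cells were not covered by this test. The axial position of the tissues may be reflected: the 22 genes of paralog groups 4 to 11 averaged 1.34 ± 1.0 (SD) in PDPN+BP3- and 1.42 ± 1.16 in PDPN- cells, and the 7 genes of groups 1 to 3 averaged -0.19 ± 0.414 and -0.36 ± 0.727, with exact one-sided permutation p of 5.00e-05 and 9.23e-05 (9.23e-05 for both after the Benjamini-Hochberg adjustment over the 2 tests), though genes of 1 cluster are not independent and the boundary between the groups was chosen after their values were seen.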

How the results depend on the processing

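The alternatives were set before the data were examined, except for the shared directions without thymus PDPN+BP3- replicate 1, chosen after seeing the data: 2528 genes with the same and 167 with opposite signs for the subset difference, and 642 and 181 for the tissue difference. Of the values of named genes under the alternatives, 8956 in all, 8777 kept their direction and their side of the threshold. Of the others 178 were no longer past it, 1 was newly past it and 0 reversed. Of the 629 named pairs past the threshold, 584 passed under every alternative run. Most of these pairs were chosen for large differences or small adjusted p, so their share does not describe all genes. Between the tissues in PDPN- cells, 1799 genes passed with all arrays and 1273 without thymus PDPN- replicate 1. No gene called both with and without cyclic loess had opposite signs, and cyclic loess moved the median of all genes by under 0.1 in every comparison.

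A threshold of at least 2-fold lowered the counts by construction. It left 1797 genes between the thymus subsets (907 higher and 890 lower in PDPN+BP3- cells) and 1657 in lymph node (985 and 672). It left 1787 for PDPN+BP3+ against PDPN- cells (1016 and 771) and 1161 against PDPN+BP3- cells (604 and 557). Between the tissues it left 943 in PDPN+BP3- cells (549 higher and 394 lower in lymph node) and 603 in PDPN- cells (337 and 266), and 1184 for the interaction, 676 of them higher. With at least 2-fold in both, 1010 genes shared the direction of the subset difference in both tissues and 25 had opposite signs, and for the tissue difference in both subsets these were 173 and 34.

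Cyclic loess gave 2178 lower genes between the thymus subsets, 1343 higher and 1573 lower genes between the tissues in PDPN+BP3- cells, and 871 higher and 1193 lower for the interaction. With only the arrays of the compared populations, which leaves fewer residual degrees of freedom, 1430 genes were higher in lymph node PDPN+BP3- cells. Leaving out each array in turn, that count ranged from 1381, without thymus PDPN+BP3- replicate 1, to 2538. Apart from the effect of the 2-fold threshold the cause was not tested.

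The labels do not say that equal replicate numbers were sampled together, and the main model treats the arrays as unpaired. The correlation of equal numbers was not above 0.1 throughout any comparison, at -0.174 to -0.142 between the thymus subsets. Between PDPN+BP3- and PDPN- cells of the lymph node it averaged 0.146. Between PDPN+BP3+ and PDPN+BP3- cells it was 0.0639 to 0.154. Between PDPN+BP3+ and PDPN- cells it averaged -7.32e-04. These correlations were taken on deviations from the population mean, which cancel out within a population. The means for unequal numbers, -0.0742 and -0.0487 in the first 2 of these comparisons, follow from that and do not bear on pairing. Whether lymph node arrays of equal number share an experiment therefore stays open. A replicate block gave 5313, 4315, 5118 and 3044 genes for the subset comparisons in the order above, 3264 and 1776 for the tissues and 2357 for the interaction. It left 172 of 174 list results on the same side of the threshold, and 2 lists were newly called.

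Of the 84 list shifts called, 80 were also called after cyclic loess, which ended those of cell cycle genes between the thymus subsets, retinoid metabolism between PDPN+BP3- and PDPN- cells of the lymph node, complement between the tissues in PDPN+BP3- cells and endothelium between the tissues in PDPN- cells. Leaving out genes with low values ended these 4 and 6 more: complement and endothelium between PDPN+BP3- and PDPN- cells of the lymph node, Notch signalling between PDPN+BP3+ and PDPN- cells, class I antigen presentation between PDPN+BP3+ and PDPN+BP3- cells, and pericytes and smooth muscle and the pharyngeal and cardiac factors between the tissues in PDPN- cells. With fry 5 did not pass: cell cycle between the thymus subsets and between the tissues in PDPN+BP3- cells, interstitial matrix between the tissues in PDPN+BP3- cells, and endothelium between PDPN+BP3- and PDPN- cells of the lymph node and between the tissues in PDPN- cells. Newly called were 33 list results with fry, 7 with cyclic loess and 1 with genes with low values left out. The mesothelium list was not tested with those genes left out, since fewer than 4 of its members remained. Leaving out 1 array moved the median of a called list, or its number of members past the threshold, by over 1.5 times in 22 of the 84 shifts. The number of arrays, and the signal over background of genes near the lower end of the scale, limit what small differences can be called.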

Other observations

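The lists and their tests were set before the data were examined, and the remarks on single arrays and on Blnk, Xist and Bst1 were chosen after their values were seen. B cell, myeloid, adipocyte and glia lists, and the genes of the X inactivation centre and the Y chromosome, were not called by camera on all arrays in any of the 6 comparisons. This statement does not extend to fry. Of 9 B cell genes 0 passed in both tissue comparisons, with medians of 0.02 and -0.01 (adjusted p 0.818 and 0.941), and Blnk was higher in PDPN+BP3+ than in PDPN+BP3- cells (1.10). For B cells the sign of the median, mean and test differed in 5 of the 6 comparisons. Of 15 myeloid genes 5 were higher and 2 lower in PDPN+BP3- against PDPN- cells of the lymph node (8 and 3 adjusted over the list alone; median 0.30, adjusted p 0.154), with Cd14 at 2.69 ± 0.25. Of 9 adipocyte genes 5 were lower and 1 higher between the thymus subsets (5 and 1 adjusted over the list alone; median -0.37, adjusted p 0.0694, and 0.0449 without thymus PDPN+BP3- replicate 1), with Fabp4 at -3.92 ± 0.25 and the nuclear receptor Pparg at -3.69 ± 0.15. Of 6 glia genes 2 were higher and 1 lower in lymph node PDPN+BP3- cells against those of thymus (2 and 1 adjusted over the list alone; median -0.08, mean 0.34, adjusted p 0.967), with S100b at 2.35 ± 0.18. Both measured genes of red blood cells were too few for a test and had medians from -0.26 to 0.11. Of 4 sex-linked genes 0 passed between the tissues on all arrays (adjusted p 0.808 in PDPN+BP3- and 0.809 in PDPN- cells). Without thymus PDPN+BP3- replicate 1, 1 of them was higher in lymph node PDPN+BP3- cells. Xist averaged 6.53 and 6.43 in the thymus populations and 7.52 to 7.80 in those of the lymph node. The 4 sort antigen genes as a list were called between PDPN+BP3+ and PDPN+BP3- cells, which were sorted on BP3 itself (3 higher; median 0.75, adjusted p 5.15e-04, adjusted p = 0.0692 with an estimated correlation).

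Further shifts were called with the preset correlation only. Between PDPN+BP3- and PDPN- cells of the lymph node, 8 of 19 chemokine genes (1 lower adjusted over the list alone; median 0.27, adjusted p 0.00131, adjusted p = 0.218 with an estimated correlation) and 4 of 7 complement genes (median 0.44, adjusted p 0.00678, adjusted p = 0.218 with an estimated correlation) were higher. The chemokine median was 0.16 without PDPN+BP3- replicate 1, 0.48 without its replicate 2 and 0.12 without PDPN- replicate 3. Between PDPN+BP3+ and PDPN- cells 8 of 19 chemokine genes were higher and 1 lower (8 and 5 adjusted over the list alone; median 0.29, adjusted p 0.00359, adjusted p = 0.251 with an estimated correlation), with a median of 0.45 without PDPN- replicate 2. Between PDPN+BP3+ and PDPN+BP3- cells 6 of 15 basement membrane genes (median -0.34, adjusted p 2.58e-06, adjusted p = 0.177 with an estimated correlation) and 9 of 14 immediate early genes (11 adjusted over the list alone; median -0.52, adjusted p 1.16e-06, adjusted p = 0.179 with an estimated correlation) were lower. Of the immediate early genes 4 were lower without PDPN+BP3+ replicate 1, and 5 without its replicate 2 or without PDPN+BP3- replicate 2. Between the tissues in PDPN+BP3- cells, 9 of 17 NF-κB targets (1 lower adjusted over the list alone; median 0.54, adjusted p 4.65e-04, adjusted p = 0.297 with an estimated correlation) and 6 of 13 Notch genes (median 0.47, adjusted p 6.24e-04, adjusted p = 0.147 with an estimated correlation) were higher in lymph node, and 7 of 22 cell cycle genes were lower (9 adjusted over the list alone; median -0.38, adjusted p 1.18e-04, adjusted p = 0.432 with an estimated correlation). The Notch median was 0.75 without lymph node replicate 3, and of the cell cycle genes 2 were lower without lymph node replicate 1 and 4 without lymph node replicate 3 or thymus replicate 3. On thymus PDPN+BP3- replicates 1, 2 and 3 the cell cycle mean was 4.76, 5.11 and 5.32. The T lineage mean was 3.19, 4.39 and 4.51 on the same arrays. Whether RNA of thymocytes adds to the cell cycle difference was not tested. Interferon response genes were lower in lymph node PDPN+BP3- cells than in those of thymus (adjusted p 1.18e-04 by camera). Without thymus PDPN+BP3- replicate 1, 7 of 19 were lower and 1 higher (median -0.52). In PDPN- cells 2 of 7 complement genes (median 0.24, adjusted p 8.10e-04, adjusted p = 0.152 with an estimated correlation) and 4 of 19 interferon response genes (5 adjusted over the list alone; median 0.30, adjusted p 9.89e-04, adjusted p = 0.349 with an estimated correlation) were higher in lymph node, the interferon median being 0.15 without lymph node replicate 1.

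When 1 array was left out, 10 list calls ended, all of which were also lost with an estimated correlation. Cell cycle genes were lower between the thymus subsets (6 of 22, median -0.40, adjusted p 0.026, adjusted p = 0.677 with an estimated correlation), with an adjusted p of 0.0955 without thymus PDPN+BP3- replicate 1 (3 lower and 1 higher, median -0.24) and 0.0705 without thymus PDPN- replicate 3. Complement genes were higher there (3 of 7, with 1 lower, adjusted p 0.0364, adjusted p = 0.324 with an estimated correlation), with 0.0586 without thymus PDPN+BP3- replicate 2 and 0.0645 without thymus PDPN- replicate 3. Endothelium genes were higher between PDPN+BP3- and PDPN- cells of the lymph node (8 of 19, with 1 lower, median 0.32, adjusted p 0.0338, adjusted p = 0.449 with an estimated correlation), with 0.104 without PDPN+BP3- replicate 1 (median 0.20), 0.103 without PDPN- replicate 3 (4 higher) and 0.0523 without PDPN+BP3- replicate 3. Retinoid metabolism, at 0.0491 in that comparison (adjusted p = 0.288 with an estimated correlation), had 0.0683, 0.0528 and 0.0521 without lymph node PDPN- replicates 1, 2 and 3 and 0.0601 without PDPN+BP3- replicate 1. Notch signalling, at 0.0447 between PDPN+BP3+ and PDPN- cells (adjusted p = 0.348 with an estimated correlation), had 0.0653 without PDPN- replicate 3 and 0.0552 without PDPN+BP3+ replicate 2. Class I antigen presentation, at 0.0111 between PDPN+BP3+ and PDPN+BP3- cells (adjusted p = 0.385 with an estimated correlation), had 0.0506 without PDPN+BP3+ replicate 1 and 0.0523 without PDPN+BP3- replicate 3. Between the tissues in PDPN+BP3- cells, interstitial matrix, at 0.0272 (adjusted p = 0.475 with an estimated correlation), had 0.0719 without thymus replicate 2 and 0.0795 without lymph node replicate 3, its median turning from -0.02 to 0.02 in both cases. Complement, at 0.0473 there (adjusted p = 0.349 with an estimated correlation), had 0.0532 and 0.0637 without thymus replicates 1 and 3 and 0.0641 and 0.0518 without lymph node replicates 1 and 2. Between the tissues in PDPN- cells, basement membrane, at 0.0104 (adjusted p = 0.432 with an estimated correlation), had 0.0773 without lymph node replicate 2. Endothelium, at 0.0459 there (adjusted p = 0.478 with an estimated correlation), had 0.0801 and 0.0521 without thymus replicates 1 and 2 and 0.254 and 0.0655 without lymph node replicates 1 and 2.

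Lymph node PDPN+BP3- replicate 1 stood apart in the B cell list, with a mean of 3.08 against 2.37 and 2.38 on the other arrays of its population, and in Bst1, at 3.80 against 3.03 and 3.06. Glycam1 averaged 7.38 ± 3.06 (SD) in lymph node PDPN- cells, 8.70 in PDPN+BP3+ and 9.88 in PDPN+BP3- cells, and 2.82 and 2.85 in the thymus populations.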
